A study of Mus musculus with 4 samples.

How the data were processed

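RNA was measured in bone marrow-derived macrophages (BMDMs) grown from C57BL/6 mouse bone marrow over 5 to 7 days in medium with 30% L929-conditioned medium, which drives macrophage differentiation. Per the labels, the cells were left unexposed or were exposed for 16 h to extracellular vesicles (EVs) from Beas2B, a human lung epithelial cell line, carrying a scrambled RNA or a mimic of miR-17 or of miR-93. RNA of 4 biological replicates was pooled for each library, so each of the 4 groups was 1 library and the spread between cultures was not measured. RNA was isolated with miRNeasy Mini kits, and libraries were made with the Ion Total RNA-Seq Kit v2, per the labels. Groups were taken from the transfection label of each sample. No paired or replicate structure was present in the labels.

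The deposited table of raw values gave the count of reads for 38087 genes in each library as whole numbers that were not normalized, per the file headers. The same deposited table gave the average coverage per base of each gene, a signal not scaled to library size, and the GC content of each gene in percent. The deposited gene length was the whole span from gene start to gene end in 38087 of 38087 genes, so the counts were treated as covering introns as well as exons. The authors' log2 values in a further deposited table were centred on the median of the 4 libraries for each gene, a property that held for 38087 genes within 1e-05. The authors' deposited log2 fold changes for 5 of the 6 pairs were differences of these log2 values, and 10 deposited lists held the genes past a 2-fold difference. The submitters' processing notes name the mm10 genome build and DESeq, with no versions. The aligner, the gene annotation and the treatment of strand are not given in the sources used here. Reads of genes that overlap, or that have near-identical copies such as ribosomal protein pseudogenes, can therefore have been shared or split between them, and values of such genes are uncertain.

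The authors' log2 values were not a rescaling of the deposited counts. Across genes, log2 ratios computed from the counts and those taken from the authors' values had Pearson correlations of 0.508 to 0.590, and 317 of 14618 genes with at least 20 reads in every library had an authors' value of 0 in all libraries. The counts were used for the main values, and the authors' values served as an alternative.

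Libraries held 17815250 to 22607247 reads in genes. They were scaled with DESeq-type median-of-ratios size factors, which were 0.949 for unexposed, 0.854 for control EV, 1.13 for miR-17 EV and 1.10 for miR-93 EV. A log2 ratio was taken as log2 of normalized count plus 1, and each ratio of counts has a 95% exact conditional (Clopper-Pearson) interval. PCR reads without molecular identifiers are not independent molecules, so these intervals cover counting error only. A gene counted as higher or lower in a pair when the ratio was at least 2-fold, the mean of the pair was at least 20 normalized counts and the interval excluded 1. Counting error alone was simulated 20 times per pair with unchanged genes. On simulated data with counting error only and 200 genes changed, this rule recovered 47.0% to 52.0% of genes changed 2-fold. It recovered 99.5% to 100% of those changed 3-fold. The changed genes were drawn only from genes well above the minimum of 20 normalized counts, so recovery near that minimum was not measured.

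Before the data were examined, 32 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Named genes were up to 15 per direction for responses shared by all exposed libraries or by both mimic libraries, up to 5 per direction for each pair, up to 4 per gene list, and the miR-17 and miR-93 loci with their host genes. Shared and pairwise genes needed a mean of at least 100 normalized counts, and unnamed gene models, small RNAs and pseudogenes were only counted. A list was described where at least 5 members had a mean of at least 20 normalized counts, which held for 20 lists. Its median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, and a list was called apart in the outer 2.5% on either side. Members of each list were also resampled 1000 times for an interval of the percentile, a step chosen after seeing the percentiles. Of lists of randomly drawn genes, 1 of 20 is outside these bounds in a pair. Lists whose members vary together can be outside more often without an effect of the condition. That rate could not be measured with 1 library per group. In the check on simulated data for control EV against unexposed, with counting error only, 2 of 40 unchanged lists of 30 random genes were outside. All 40 of 40 lists raised 1.1-fold were outside.

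Sites for the miR-17 family were sought in the longest annotated 3' UTR of each gene in GENCODE M21, whose identifiers matched 95.3% of the genes. A site was GCACTTT, the complement of the seed shared by miR-17-5p and miR-93-5p, or the longer GCACTTTA. Genes with a site were compared with random genes matched on expression, and as an alternative also on 3' UTR length. In simulated counts of miR-17 EV against control EV, a 1.05-fold repression of 1796 genes with a site gave a median of −0.07 and a percentile of 0.

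Pooled models were a secondary description. Quasi-likelihood tests in edgeR 4.0.16 with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05 compared the 3 exposed libraries with unexposed, and both mimic libraries with control EV. Libraries with different cargo are not replicates, and the lone library of each comparison was assumed to vary like the others. DESeq2 1.42.0 was the other tool. With 200 genes changed 2-fold in simulated data, edgeR recovered 66.5% for any EV and 79.5% for both mimics against control EV. Relations between pairs that share a library were set beside values simulated 20 times with unchanged libraries and beside the overlap of independent lists.

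Alternatives fixed in advance were other scalings (TMM and total counts), other pseudocounts (0.5 and 5), no filter or a minimum of 100 normalized counts, 10 expression bins, only the longer seed site, random genes matched also on 3' UTR length, the authors' fold changes for named genes, and leaving out each exposed library in a pooled model. Alternatives chosen after seeing the data were a correction of log2 ratios on GC content or on transcript length, leaving out near-identical copies and genes overlapping them, random lists of protein-coding genes or matched on transcript length, and the authors' values for lists and seed sites. A list of targets of the fatty acid receptor PPAR was also added after Angptl4 had been seen. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.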

Results

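The transcriptome of mouse bone marrow-derived macrophages was measured after contact with extracellular vesicles (EVs), the membrane particles that cells release. The 4 groups were unexposed cells and cells exposed for 16 h to EVs of the human lung epithelial line Beas2B carrying scrambled control RNA (control EV), miR-17 mimics (miR-17 EV) or miR-93 mimics (miR-93 EV). Each group was 1 library made from the pooled RNA of 4 biological replicates. No group had a replicate library, so ratios compare the libraries, not the conditions, and their 95% intervals cover counting error only. Reads in genes numbered 19705482 for unexposed, 17815250 for control EV, 22607247 for miR-17 EV and 22247527 for miR-93 EV, and 24637 to 26037 genes had at least 1 read. Single genes are called higher or lower where the ratio of normalized counts was at least 2-fold, whereas members of gene lists are counted as higher or lower by any amount. Coordinates are those of the mm10 build. Aligned bases per read were computed for each gene with a mean of at least 100 reads, from its average coverage, span and reads. Their medians over genes were 114 in control EV, 103 in unexposed, 96.4 in miR-17 EV and 98.7 in miR-93 EV.

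The labels name miR-17 and miR-93, and the mouse loci of both were looked at in each library. Mir17hg, the host transcript of miR-17 (chromosome 14, 115042879 to 115046727), had 22.1 normalized counts in unexposed, 39.8 in control EV, 35.5 in miR-17 EV and 42.5 in miR-93 EV. Mcm7, the replication helicase gene that hosts miR-93 (chromosome 5, 138164583 to 138172422), differed from unexposed by log2 ratios of −0.02, −0.04 and −0.06 in control EV, miR-17 EV and miR-93 EV, and its span overlaps Cops6. The Mir17 and Mir93 loci themselves had means of 0.75 and 3.25 reads per library. These reads come from precursor loci, and mature miRNAs or mimics were not measured by them.

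Exposure to EVs of any cargo was compared with no exposure. Angptl4, which encodes a secreted inhibitor of lipoprotein lipase (ENSMUSG00000002289, chromosome 17, 33773750 to 33781575), was higher in each exposed library. Its normalized count was 136 in unexposed, 439 in control EV, 326 in miR-17 EV and 320.5 in miR-93 EV, which gave ratios of 3.21 (95% interval 2.64 to 3.98), 2.39 (1.96 to 2.95) and 2.35 (1.92 to 2.91). The other genes higher in all 3 exposed libraries were Iqck and the zinc finger genes Zfp128, Zfp873 and Zfp963, which had 13.7 to 30.6 normalized counts in unexposed and were picked out after their values were seen. Iqck and Zfp963 overlap other genes. No gene was lower in all 3 exposed libraries under the same rule. A pooled edgeR quasi-likelihood test called 0 of 18206 genes higher and 0 lower, with 452 at an unadjusted p under 0.05. DESeq2 called 1 gene, Angptl4, at an adjusted p of 0.00969 and a log2 ratio of 1.41 in edgeR. Without control EV, edgeR called many more genes in each direction than without miR-17 EV. The spread in that fit comes only from the difference of miR-17 EV and miR-93 EV, the pair with the fewest differences. Its calls therefore do not measure a response to EVs.

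The response to EVs with scrambled RNA was read from control EV against unexposed. Here 75 genes were higher and 121 lower of 15294 tested, against means of 11.7 and 13.2 from counting error alone, and 93.0% of tested genes lay within 1.5-fold. Besides Angptl4, the gene with the largest ratio among the higher named genes was Crip1, which encodes a small LIM-domain protein (chromosome 12, 113152012 to 113153877), at 1114 normalized counts in unexposed and 2351 in control EV. Lower genes included Cd209f, a C-type lectin (chromosome 8, 4102787 to 4105835; log2 ratio −2.03), Kcnn3, a calcium-activated potassium channel (chromosome 3, 89520164 to 89667761; −1.43), and Cobl, an actin nucleator (chromosome 11, 12236608 to 12464960; −1.28). Stk39, a kinase that regulates ion cotransport (chromosome 2, 68210445 to 68472268), had a log2 ratio of −1.07. The authors' log2 values of Cobl were 0 in every library.

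Cell cycle genes stood higher in control EV than in unexposed. Of 40 measured members 33 were higher and 7 lower by any amount and none by 2-fold, with a median log2 ratio of 0.21 at percentile 100. Examples were the mitotic cyclin Ccnb2 (0.66), the mitotic kinases Plk1 (0.54) and Aurka (0.49), and the kinesin Kif20a (0.49). Interferon-stimulated genes stood lower, with 38 of 47 members lower, a median of −0.15 and percentile 0. Among them were the RNA sensor Ifih1 (−0.52), the kinase Eif2ak2 (−0.67) and Ifi204 (−0.53). Integrin, adhesion and migration genes were lower in 25 of 35 members (median −0.10, percentile 0.590), with the matrix proteases Mmp9 (−0.90), Mmp8 (−0.78) and Mmp13 (−0.62) lowest. Cytosolic ribosomal protein genes were lower in 48 of 78 members (median −0.08, percentile 0.150), led by Rplp1, a ribosomal stalk protein (chromosome 9, 61913284 to 61914538), with 14536 normalized counts in unexposed and 6172 in control EV. Of 21 measured markers of other cell types 15 were lower by any amount in this pair, which were all of the B cell, erythroid, T and NK cell and epithelial markers, 3 of 4 fibroblast, 2 of 3 osteoclast, 2 of 3 neutrophil, 1 of 3 dendritic cell and 1 of 2 mast cell markers. The lowest of the dendritic cell, fibroblast, osteoclast and neutrophil markers were Fscn1 (−1.15), Col1a1 (−1.10), Acp5 (−0.95) and Lcn2 (−0.67). Ribosomal protein genes have many near-identical pseudogenes, and pseudogenes took 9.05% of reads in control EV against 8.17% in unexposed. Without near-identical copies and genes overlapping them, an alternative chosen after seeing the data, 38 genes were higher and 67 lower.

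**Figure D1:**
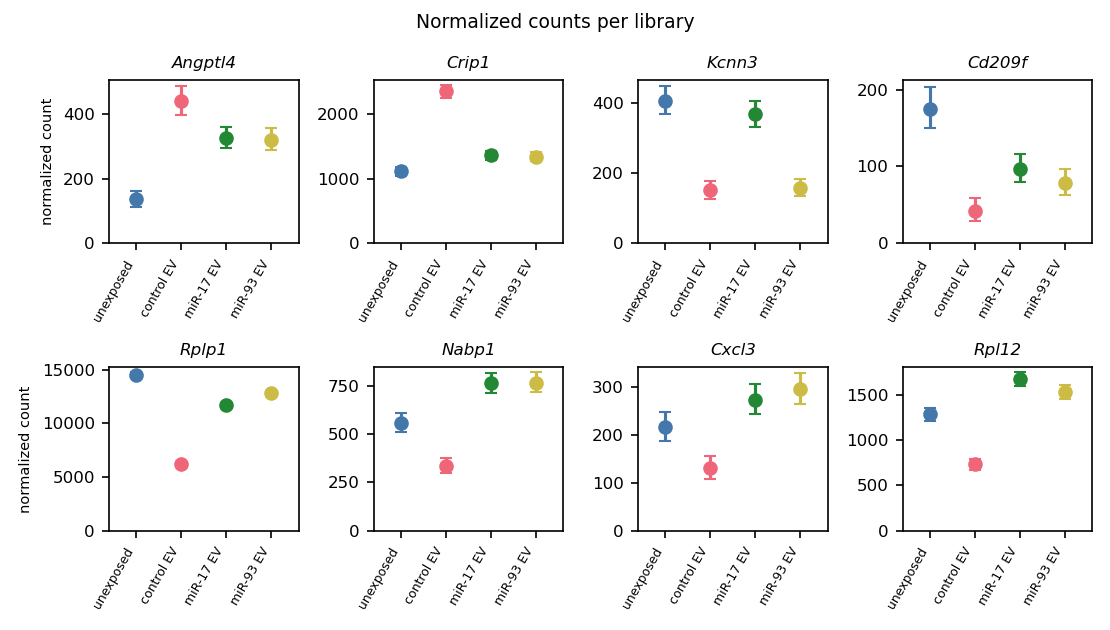
Normalized counts (vertical axis, linear, from 0) of 8 named genes in the unexposed, control EV, miR-17 EV and miR-93 EV libraries; points are single libraries, bars are exact Poisson 95% intervals of counting error, and the 8 genes were picked from the named genes after their values were seen. Angptl4 was at 136 in unexposed and at 320.5 to 439 in the exposed libraries, and Nabp1 was lowest in control EV at 337.

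EVs with each mimic were then compared with unexposed cells. In miR-17 EV 45 genes were higher and 28 lower of 15396, and in miR-93 EV 55 were higher and 28 lower of 15403. Counting error alone gave means of 7.45 and 7.65 in miR-17 EV and of 8.45 and 9.40 in miR-93 EV. Both mimic libraries shared 14 higher genes, among them Angptl4 and the serotonin receptor gene Htr2b (chromosome 1, 86099026 to 86111970), and 3 lower genes, 1700009P17Rik, Gm14081 and Gm15532, named after their values were seen. Htr2b had 65.3 normalized counts in unexposed, 71.4 in control EV, 189.9 in miR-17 EV and 174 in miR-93 EV. It lies in the span of Psmd1, which had a mean of 3339.5 reads, and in the authors' log2 values the direction for miR-17 EV was the opposite, at −0.27 against unexposed and −0.48 against control EV. Kcnn3 was lower in miR-93 EV (log2 ratio −1.35) but had a log2 ratio of −0.15 in miR-17 EV, and Cd209f had log2 ratios of −0.85 in miR-17 EV and −1.14 in miR-93 EV. With scaling to total counts the split was 61 higher and 21 lower in miR-17 EV and 69 higher and 21 lower in miR-93 EV.

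Genes of antigen presentation and LXR targets stood lower, and genes of protein synthesis and antioxidant defence higher, in both mimic libraries than in unexposed. MHC class II presentation genes were lower by any amount in 8 of 9 members in each and by 2-fold in none, with medians of −0.28 at percentile 0.310 in miR-17 EV and −0.30 at percentile 0.130 in miR-93 EV. H2-Aa, an MHC class II chain, had log2 ratios of −0.94 and −0.89. The dendritic cell markers Fscn1 and Itgae had log2 ratios of −0.46 and −0.22 in miR-17 EV and −0.30 and −0.40 in miR-93 EV. Both measured B cell markers were also lower in each library, with medians of −0.38 and −0.42. Of 21 markers of other cell types, 8 were higher and 13 lower in miR-17 EV, and 9 higher and 12 lower in miR-93 EV. All 3 osteoclast markers were lower in miR-17 EV (median −0.26). Both mast cell markers were higher in each library (medians 0.10 and 0.48), and both erythroid markers in miR-93 EV (median 0.34). LXR targets and lipid efflux genes were lower in 10 of 13 members in miR-17 EV (median −0.22, percentile 0.0200) and in 8 of 13 in miR-93 EV (−0.16, percentile 1.37), with the fatty acid synthase gene Fasn at −0.49 and −0.43 and the cholesterol exporter gene Abca1 at −0.45 and −0.29. When members were resampled, the LXR percentile ranged from 0 to 49.4 in miR-17 EV and from 0 to 99.7 in miR-93 EV. Cholesterol biosynthesis genes were lower in 17 of 23 members in miR-93 EV (median −0.13, percentile 0.610), among them Mvk (−0.46). NRF2 antioxidant genes were higher in 15 of 18 members in each library (medians 0.09 and 0.14, percentiles 99.98 and 100), with Gclc, which catalyses the limiting step of glutathione synthesis, at 0.45 and 0.46. Cytosolic ribosomal protein genes were higher in 64 of 78 members in miR-17 EV and 62 in miR-93 EV (medians 0.17 and 0.11, percentile 100 in both), and nuclear oxidative phosphorylation genes in 39 and 35 of 61 (medians 0.06 and 0.04, percentiles 99.98 and 99.2). Across 15386 genes, log2 ratios to unexposed had Spearman correlations with GC content of −0.29 in miR-17 EV, −0.31 in miR-93 EV and 0.04 in control EV, where genes are not independent replicates.

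Other lists were apart in only one of these comparisons, a difference that was not tested and that in part depended on the settings. In miR-17 EV the inflammatory cytokines and chemokines had a median of 0.12 (percentile 99.4), with 14 members higher and 11 lower, Ccl5 at 0.99 and Cxcl2 at 0.63. Integrin, adhesion and migration genes had a median of −0.12 (percentile 0.605, 23 of 35 lower), and replication-dependent histones −0.29 (percentile 0.390, 7 of 11 lower). When members were resampled, these percentiles ranged from 26.1 to 100 for cytokines, from 0 to 94.2 for integrins and from 0.0900 to 89.1 for histones. In miR-93 EV the genes of the unfolded protein and integrated stress response had a median of 0.09 (percentile 99.6, 13 of 21 higher), with Dnajb9 at 0.45 and Chac1 at −0.54, and with a minimum of 100 normalized counts the same list was at 99.01 in miR-17 EV. Of the 33 list calls over all pairs, 23 had a resampling interval that reached past the bound. Of the 10 others, those of cell cycle were in control EV against unexposed and in miR-93 EV against control EV. The rest were those of ribosomal protein and NRF2 genes in both mimic libraries against either reference. Leaving out near-identical copies was tried only for counts of genes, so the ribosomal protein calls were not examined for reads shared with pseudogenes. Pseudogenes took 8.17% of reads in unexposed, 9.05% in control EV, 7.96% in miR-17 EV and 8.23% in miR-93 EV. Several calls also ended under an alternative. With a minimum of 100 normalized counts, the percentile was 60.4 for cytokines in miR-17 EV and 13.6 for MHC class II in miR-93 EV. In miR-93 EV the LXR list moved to 12.6 after a correction on GC content, and with matching on transcript length it moved to 2.60 and oxidative phosphorylation to 92.0. In the authors' log2 values MHC class II moved to 5.34 and integrins to 8.61 in miR-17 EV, and in miR-93 EV MHC class II moved to 16.1, LXR to 8.39 and cholesterol biosynthesis to 3.53.

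**Figure D2:**
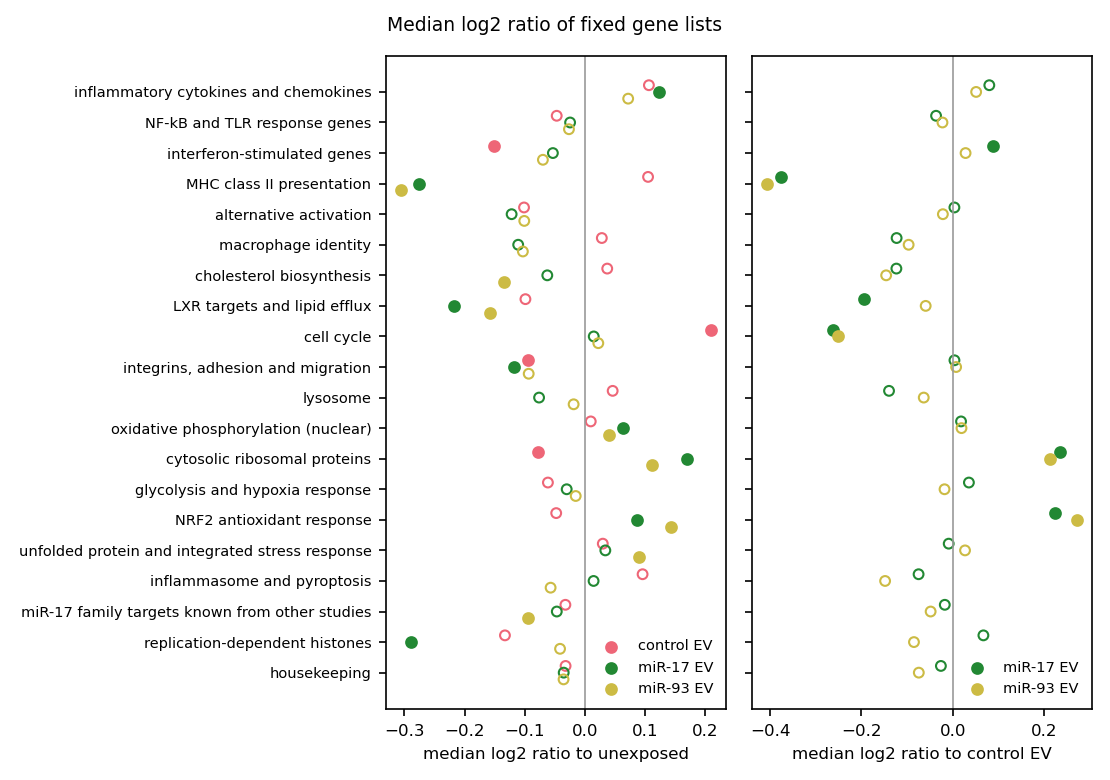
Median log2 ratio (horizontal axes) of the 20 gene lists with at least 5 measured members, against unexposed on the left and against control EV on the right, with 1 point per library and list. Filled points are medians in the outer 2.5% of matched random lists on either side and open points are the others; in control EV cell cycle was at 0.21 and interferon-stimulated genes at −0.15, and MHC class II was at −0.28 and −0.30 in the mimic libraries against unexposed.

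Each mimic library was also set against control EV. This contrast holds whatever set the single control EV library apart, as well as any contribution of the mimics. In miR-17 EV 162 genes were higher and 70 lower of 15362, and in miR-93 EV 153 were higher and 71 lower of 15361, against at most 19 per direction from counting error alone. Both libraries shared 68 higher genes, of which 33 are protein-coding and 22 pseudogenes, and 27 lower genes, of which 8 are protein-coding and 12 pseudogenes. Of these, only Htr2b was also higher, and only Gm15532 also lower, in both mimic libraries against unexposed under the same rule. Nabp1, a single-stranded DNA-binding protein gene (chromosome 1, 51469498 to 51478399), had 337 normalized counts in control EV, 766 in miR-17 EV and 769.5 in miR-93 EV, against 559.6 in unexposed. Cxcl3, a neutrophil-attracting chemokine gene (chromosome 5, 90786103 to 90788086), had log2 ratios of 1.07 and 1.18, and the ribosomal protein gene Rpl12 (chromosome 2, 32961559 to 32964496, overlapping Lrsam1) 1.19 and 1.06. Lower in both were Rasl2-9, which encodes a relative of the GTPase Ran (chromosome 7, 5124945 to 5125950; −1.26 and −1.09), and Gphn, the gephyrin gene (chromosome 12, 78226655 to 78684767; −1.06 and −1.15), whose authors' values differed by only −0.18 and −0.03. Lrrc66 (−1.19 in miR-17 EV and −0.93 in miR-93 EV), the exonuclease gene Exo1 (−1.02 and −0.89) and Cdkn3, a phosphatase acting on cyclin-dependent kinases (−0.997 and −1.16), had similar ratios in both libraries and passed 2-fold in 1 of them. For Nabp1, Cxcl3, Rpl12, Rasl2-9 and Gphn, control EV also differed from unexposed, by log2 ratios of −0.73, −0.73, −0.81, 0.85 and 0.90.

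Relative to control EV, cell cycle genes were lower in both mimic libraries, in 29 of 40 members in miR-17 EV and 32 in miR-93 EV (medians −0.26 and −0.25, percentile 0 in both). Against unexposed the same genes had medians of 0.01 and 0.02 at percentiles 78.5 and 79.1, where control EV had a median of 0.21. The kinesin Kif2c had log2 ratios of −0.68 and −0.69 and the checkpoint kinase Bub1b −0.61 and −0.64. MHC class II presentation genes were lower in 9 of 9 and 8 of 9 members (medians −0.38 and −0.41, percentiles 0.2 and 0.06), with H2-Aa at −1.11 and −1.06 and the invariant chain Cd74 at −0.77 and −0.59. The dendritic cell marker Itgae had log2 ratios of −0.45 and −0.64, whereas Fscn1, another such marker, had 0.68 and 0.85. NRF2 antioxidant genes were higher in 15 and 16 of 18 members (medians 0.22 and 0.27, percentile 100 in both), among them the cystine transporter Slc7a11 (0.68 and 0.69). Cytosolic ribosomal protein genes were higher in 66 and 65 of 78 members (medians 0.23 and 0.21, percentile 100 in both). Interferon-stimulated genes were apart in miR-17 EV (median 0.09, percentile 99.9), with Ifi204 at 0.69, and stood at percentile 96.2 in miR-93 EV, or 99.1 with a minimum of 100 normalized counts. Of 21 markers of other cell types 12 were higher in each library, among them both erythroid markers (medians 0.54 and 0.71), the T and NK cell marker Il7r (0.41 and 0.57), and the neutrophil marker Lcn2 (0.85 and 0.76), and both mast cell markers were higher in miR-93 EV (median 0.55). Of the osteoclast markers 2 of 3 were lower in each, with Acp5 (0.52 and 0.69) the exception. With a minimum of 100 normalized counts MHC class II in miR-93 EV moved to percentile 3.54, and the LXR list, at percentile 1.53 in miR-17 EV, moved to 15.6 after a correction on GC content and to 18.2 in the authors' values.

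A pooled edgeR test of both mimic libraries against control EV called 2032 genes higher and 1932 lower of 18206, with 5781 at an unadjusted p under 0.05. DESeq2 called 418 higher and 348 lower, and edgeR without a filter on low counts called 0 higher and 0 lower, with 4528 at an unadjusted p under 0.05. The spread in this fit comes from the difference of the mimic libraries only.

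**Figure D3:**
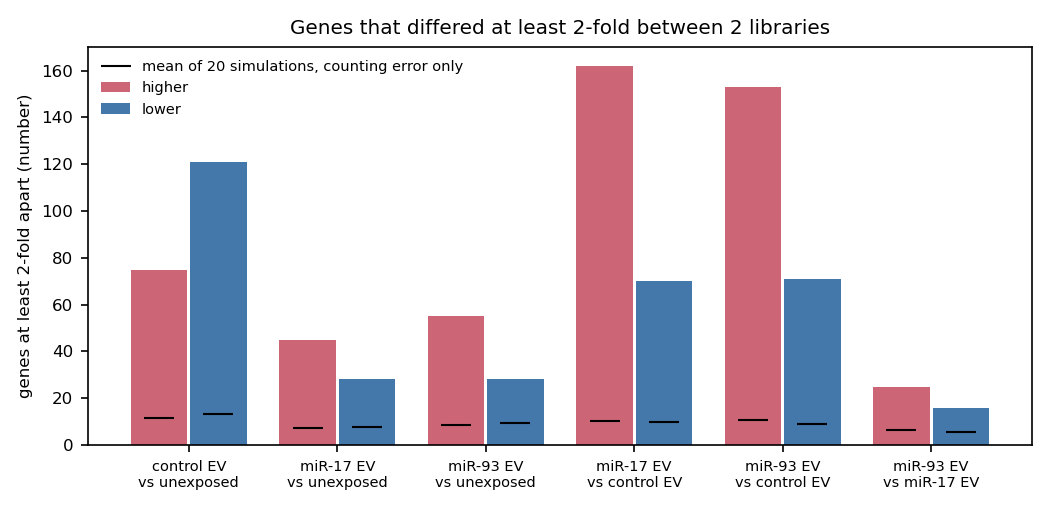
Number of genes (vertical axis, from 0) at least 2-fold higher (red) or lower (blue) in each pair of libraries, with black lines for the mean of 20 simulations of counting error alone. The pairs with control EV had the most genes, up to 162 higher and 121 lower, and miR-93 EV against miR-17 EV had 25 higher and 16 lower.

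The cargoes were compared directly in miR-93 EV against miR-17 EV, the pair with the fewest differences. There were 25 higher and 16 lower genes of 15465, against means of 6.35 and 5.70 from counting error alone, and 97.7% of tested genes lay within 1.5-fold. Kcnn3 was lower in miR-93 EV, at 159 normalized counts against 368 (log2 ratio −1.20), as was Iqcj (chromosome 3, 67892220 to 68056593), at 110.4 against 223, although the authors' difference for Iqcj was 0. Cholesterol biosynthesis genes were lower in 16 of 23 members (median −0.08, percentile 0.6). Cytosolic ribosomal protein genes were lower in 52 of 78 (median −0.04, percentile 0.0100). LXR targets were higher in 10 of 13 (median 0.06, percentile 98.0), with Abca1 at 0.16. In the authors' values the cholesterol list moved to percentile 4.30 and the LXR list to 74.7, and the LXR list was at 97.3 with a minimum of 100 normalized counts.

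Repression of miR-17 family targets was examined in lists of known and of predicted targets. Of 38 known targets, 20 were lower in miR-17 EV and 24 in miR-93 EV than in control EV, with medians of −0.02 and −0.05 at percentiles 78.4 and 54.6. Btg3, an antiproliferative gene, had log2 ratios of 0.85 and 0.75, and Hif1a, a hypoxia-responsive transcription factor gene, 0.37 and 0.40. Against unexposed the known targets were apart in miR-93 EV (median −0.09, percentile 2.49), with the cyclin gene Ccnd1 at −0.46, and this call ended at 2.54 with TMM scaling, at 22.2 after a correction on GC content, at 6.51 with matching on transcript length and at 28.1 in the authors' values. Among 12142 genes with an annotated 3' UTR, 1796 held the seed site GCACTTT and 558 of these the longer GCACTTTA. Genes with a seed site had percentiles of 99.5 in miR-17 EV and 95.4 in miR-93 EV against control EV, which moved to 22.1 and 16.0 when random genes were matched also on 3' UTR length. After a correction on GC content they stood at 47.8 and 7.76 against control EV and at 0.05 and 0.02 against unexposed, with medians of −0.02 in both. With matching on 3' UTR length as well, the values were 12.2 and 3.80 against control EV and 0.835 and 7.19 against unexposed. The shift of GCACTTT genes against control EV was ranked among the 13950 sites of 7 bases found in at least 200 genes. It stood at percentiles 47.4 and 45.7 of these, and at 21.04 and 16.1 of the 366 with the same base composition. With log2 ratios less their trend on 3' UTR length, it stood at 54.0 and 52.8, and at 42.6 and 37.7 within the same composition. A lowering of the median beyond 1.71% lay outside the intervals for both mimic libraries against either reference under these settings. These intervals resample genes with a site within single libraries, so they hold no spread between cultures and set no limit on repression.

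Pairs that share a library were set beside simulations in which nothing differed. For both mimic libraries against control EV, log2 ratios across 15386 genes had a Pearson correlation of 0.826 and a covariance of 0.103, against 0.566 and 0.0185 in simulation, and 68 higher genes were shared against 2.15 in simulation and 1.18 for independent lists. The 27 shared lower genes compared with 0.700 and 0.323. Against unexposed, the mimic libraries had a correlation of 0.686 and a covariance of 0.0472, against 0.538 and 0.0165, with 14 shared higher genes against 1.1 and 0.0780 and 3 shared lower genes against 0.550 and 0.0515. Control EV and miR-17 EV had a correlation of 0.292 and a covariance of 0.025, against 0.506 and 0.0166, with 9 shared higher genes against 1.5 and 0.111 and 3 shared lower genes against 1.1 and 0.224. Control EV and miR-93 EV had 0.313 and 0.0271, against 0.502 and 0.0165, with 11 shared higher genes against 1.25 and 0.116 and 6 shared lower genes against 0.550 and 0.223. The correlations of control EV with either mimic library lay below those in simulation, while covariances and shared genes lay above. These simulations held counting error only. Part of the excess in covariance and shared genes may come from the shared library, which is a single library and cannot be split.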

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

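The bounds of the tests below were set before their own values were seen, but the patterns were noticed in a first look at the ratios. Chosen only after results had been seen were the PPAR list, the tests on transcript length and those with miR-93 EV as the comparator. So were the spread of list percentiles, the rule that a split of members decides nothing, and the weight given to 3' UTR matching. The median over genes of aligned bases per read was 114 in control EV against 103 in unexposed. It comes from the deposited coverage and enters no comparison of expression. The labels give no sequencing or preparation batch.

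Control EV stood apart from the other libraries, with 75 genes higher and 121 lower against unexposed where miR-17 EV had 45 and 28 and miR-93 EV 55 and 28. Depth as the whole cause is argued against by thinning to equal reads, where the counts for miR-17 EV and miR-93 EV were at most 0.530 and 0.580 times that for control EV in 20 draws and a depth effect needed 0.67. A smooth trend on the deposited GC content of genes, or on transcript length, is argued against as the whole cause. After these corrections the count for control EV remained 2.60 and 2.64 times that for miR-17 EV. It remained 2.35 and 2.32 times that for miR-93 EV, with all intervals above 1.5. The GC content of the sequenced fragments was not measured, so a bias acting on them stays open. Reads of near-identical copies are argued against for miR-17 EV, where the ratio without copies was 2.39 with an interval of 1.663 to 3.475. They stay open for miR-93 EV, where it was 1.81 with an interval of 1.30 to 2.54. All these intervals treat called genes as independent and ignore the shared unexposed library, so they can be too narrow. A response to EVs with scrambled RNA, which was not tested, also stays open. So does the making of this 1 library, whose median of aligned bases per read was the highest. Each group being 1 library confounds them.

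Angptl4 was higher in all 3 exposed libraries. Reads from an overlapping gene are argued against by the annotation, which places none on its span, and by the authors' log2 values, whose smallest difference from unexposed was 1.06. A hypoxia response stays open although the glycolysis and hypoxia list in control EV, at percentile 9.45 with an upper limit of 95.03, met the bound set against it, because 11 members were higher and 12 lower, a split that decides nothing, and in miR-17 EV and miR-93 EV the intervals reached 99.96 and 99.66. A response of PPAR targets, genes driven by fatty acids, also stays open, because the 25 other targets stood at percentiles 100 and 99.9 in miR-17 EV and miR-93 EV but at 86.0 in control EV, with an interval over members of 29.6 to 100. The bound as first written counted 86.0 against the PPAR response, which is kept open because that later interval reaches past the bound. A lipid response to EVs of any cargo, which was not tested, is kept open too. All 3 ratios of Angptl4 share the single unexposed library. A low value in that library alone therefore stays open as well.

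Genes with a miR-17 family seed site were not apart as a lower group in the mimic libraries against control EV, the lowest percentile being 3.80 in miR-93 EV with GC correction and 3' UTR matching. Seed-directed repression cannot be told apart from its absence here, although the percentile of 99.5 in miR-17 EV met the bound set against it, because that percentile fell to 22.1 with an interval of 0.460 to 97.47 when random genes were matched on 3' UTR length, so the bound had measured 3' UTR length as well. A GC trend hiding a repression also stays open, since the corrected percentile was 47.8 with an interval of 1.47 to 96.0. Repression at the level of protein was not measured. Any lowering of the median was at most 1.71% within these intervals, which resample genes only. They hold no spread between cultures, so they set no upper limit on repression.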

How the results depend on the processing

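Tests on GC content, transcript length, near-identical copies, and the authors' log2 values for lists and seed sites were chosen only after the results had been seen. Of 175 log2 ratios of named genes under other settings, taken only in the pairs for which the genes were named, only the authors' values for Htr2b in miR-17 EV reversed, to −0.48 against control EV and −0.27 against unexposed, and the cause was not tested. In other pairs the authors' sign also differed, as for Lrrc66 in miR-17 EV against unexposed (−0.45 from the counts and 0.73 from the authors) and Gphn in miR-93 EV (−0.24 and 0.21). A further 10 of the 175 moved, 8 in the authors' values and 2 for Gphn with total counts. Of 120 list medians 33 were apart, of which 28 remained so under every alternative fixed in advance that could be run and 21 under all that could be run. Histones had under 5 members at a minimum of 100 and gave no value there. Resampling of members reached past the bound for 23 of the 33. In the other direction, 36 values of lists that were not apart passed the bound under an alternative, 5 of them fixed in advance. Those 5 were macrophage identity in miR-17 EV against unexposed, at 2.48 with a minimum of 100 and 2.33 with 10 bins, and with a minimum of 100 the stress response in that pair (99.01), interferon-stimulated genes in miR-93 EV against control EV (99.1) and glycolysis and hypoxia in miR-17 EV against control EV (97.97).

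Counts of higher and lower genes depended most on the filter, by its construction. In the order control EV, miR-17 EV and miR-93 EV against unexposed, miR-17 EV and miR-93 EV against control EV, and miR-93 EV against miR-17 EV, no filter gave 234 and 297, 229 and 152, 277 and 133, 391 and 191, 416 and 209, and 161 and 152. A minimum mean of 100 gave 10 and 19, 3 and 2, 2 and 2, 34 and 25, 27 and 20, and 0 and 2. A pseudocount of 5 gave 44 and 79, 20 and 17, and 30 and 12 against unexposed, 43 lower genes in miR-93 EV against control EV, and 12 and 4 in the last pair. Without near-identical copies and genes overlapping them there were 38 and 67, 27 and 17, and 34 higher genes against unexposed, and 83 and 26 and 83 and 33 against control EV. TMM scaling, total counts, a pseudocount of 0.5 and corrections on GC content or transcript length kept these counts within 1.5-fold.

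In the pooled models, DESeq2 called 1 gene higher for any EV and 418 higher and 348 lower for both mimics against control EV, and edgeR with no filter called 0 and 0 in the latter. Leaving out 1 exposed library gave 0 to 493 higher and 0 to 681 lower genes for any EV, the highest without control EV. Without control EV, the spread in this fit comes only from the difference of miR-17 EV and miR-93 EV, the pair with the fewest differences. Its calls therefore do not measure a response to EVs. No paired analysis was possible because each group is 1 library.

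The number of lists apart was 7 in control EV against unexposed and 8 in miR-93 EV against control EV after GC correction, 7 in the latter in the authors' values, and 5 in miR-93 EV against unexposed with matching on transcript length. For seed sites in miR-17 EV against control EV the percentile of 99.5 moved to 22.1 with matching on 3' UTR length. It moved to 47.8 with GC correction and to 12.2 with both (3.80 in miR-93 EV). In the authors' values, where random genes were also matched on 3' UTR length, the percentile was 36.7. For the longer site, from the counts and matched on expression only, it was 99.75 in miR-17 EV and 94.2 in miR-93 EV against control EV. In control EV against unexposed it was 2.32. After GC correction the 1796 genes with GCACTTT were at 0.05 in miR-17 EV and 0.02 in miR-93 EV against unexposed. In miR-93 EV against miR-17 EV they were at 1.35. Matching on 3' UTR length as well moved these to 0.835, 7.19 and 22.8, so only the one for miR-17 EV remained apart. The cause was not tested beyond these corrections. Depth limits genes under 20 reads, where the authors' 2-fold lists also hold most members.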

Other observations

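The PPAR list, the corrections on GC content and transcript length, and the authors' values for lists and seed sites are tests chosen only after results had been seen. Plin2, which coats lipid droplets, had 21190.0 normalized counts in unexposed, 37110.0 in control EV, 32290.0 in miR-17 EV and 32400.0 in miR-93 EV. Cpt1a, which carries fatty acids into mitochondria, had 3718, 4680.0, 4180.0 and 4261 in the same order, and the fatty acid-binding protein gene Fabp4 had 1276, 1558, 1670.0 and 1702. The 25 PPAR targets had median log2 ratios to unexposed of 0.06, 0.15 and 0.12, with 16, 17 and 19 members higher.

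Macrophage identity genes had medians of 0.03, −0.11 and −0.10 against unexposed in control EV, miR-17 EV and miR-93 EV, at percentiles 70.1, 3.87 and 6.92, with the complement gene C1qa at −0.37 in miR-17 EV. Under 5 alternatives the macrophage identity list in miR-17 EV passed the bound, at 2.48 with a minimum of 100, 2.33 with 10 bins, 1.83 among protein-coding genes, 2.23 with matching on transcript length and 0.585 in the authors' values, where miR-93 EV was at 0.780. In the same order, NF-kB and TLR response genes were at percentiles 13.8, 60.9 and 53.3, alternative activation genes at 15.6, 7.92 and 12.1, lysosomal genes at 83.2, 25.04 and 88.6, glycolysis and hypoxia genes at 9.45, 61.6 and 70.2, inflammasome and pyroptosis genes at 93.2, 76.9 and 24.1, and housekeeping genes at 23.5, 63.8 and 57.0. After a correction on GC content, the NF-kB and TLR list in miR-17 EV passed the bound, at 99.44. Saa3, an acute-phase gene, had a log2 ratio of −0.88 in control EV against unexposed.

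Markers of other cell types were few among measured genes. Measured were 3 of 15 neutrophil, 3 of 10 dendritic cell, 2 of 10 B cell, 1 of 12 T and NK cell, 2 of 12 erythroid, 2 of 9 mast cell and basophil, 4 of 13 fibroblast, 1 of 12 epithelial and 3 of 7 osteoclast markers. In control EV against unexposed, Acp5 had a log2 ratio of −0.95, Lcn2 −0.67, Fscn1 −1.15, Cd79b −0.15, Il7r −0.31, Car1 −0.50, Cpa3 −0.29, Col1a1 −1.10 and the epithelial gene Sfn −0.001. The non-coding RNAs Malat1 and Gas5 had log2 ratios of 0.20 and 0.26 there. No transcript of the mitochondrial genome was matched by name, so this sign of RNA quality gave no value.

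The authors' deposited lists of 2-fold differences held 1341 higher and 1632 lower genes for control EV against unexposed, and 65.6% to 76.8% of the genes in their 10 lists had a mean under 20 reads. The libraries were not copies of one another, since chi-square per degree of freedom across genes was lowest, at 3.39, between miR-93 EV and miR-17 EV and highest, at 19.0, between miR-17 EV and control EV.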
